A study of Oryza sativa with 4 samples.

How the data were processed

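Total RNA from the stem bases of 22 day old rice plants of genotypes G95 and G160 was labelled with biotin and hybridised to Affymetrix arrays, with 2 arrays per genotype, per the labels' protocols. The deposited value table holds log2 expression values for 41770 probe sets on each of the 4 arrays. The log2 scale was read from the values, which ran from 1.45 to 12.59, and column quartiles that nearly coincide show that the arrays were normalized together before deposit. Affymetrix Expression Console, RMA and MAS5 are named in the submitters' processing notes, with no version or role. Which of them made the table, and the background correction, are not given in the sources used here. Array scanner files and detection calls were not used here, so no level is called present or absent.

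Every probe set was kept, without a filter and without further normalization. Control probe sets were to be left out, but the probe set numbers do not tell them apart, so they stayed in. Probe sets were named from the platform annotation given for this series, and symbols and synonyms were updated by gene identifier through a reference table of assembly ASM3414082v1, which matched 14661 of 14662 genes. That table was used for names and for the order of neighbouring genes only. Of the genes, 1959 have a name other than a locus number and 607 have more than 1 probe set. The brightest probe set stood for a gene. Members of multigene families, such as the trypsin inhibitors, chitinases, germin-like proteins, lectins, histones and ribosomal proteins, can cross-hybridize, and sequence differences between the genotypes and the probes change a signal with no change in transcript level. The levels of single genes are uncertain in both respects.

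G160 was compared with G95 by limma 3.58.1 in R 4.3.3, with lmFit and eBayes at their default prior and genotype as the only term, which leaves 2 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all probe sets or all genes tested, and the threshold was 0.05. The labels call the replicates biological, and the p-values measure the spread between 2 pools per genotype. Gene lists were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry. Camera compares a list with the other genes, while fry asks whether a list's genes move one way on balance and does not compare it with other genes. With an estimated correlation, camera takes its p from the residual degrees of freedom, 2 without the block and 1 with it. It then has little power. The self-test drew simulated arrays for 41770 probe sets, 200 of them changed, in 5 runs, for G160 minus G95. Without the block, limma recovered 0% of changes of 1 log2 unit, 0.8% of 2 units, 52.4% of 3 units and 72.8% of 4 units. With the repetition as a block it recovered 0%, 71.2%, 93.6% and 95.6%, given a repetition effect that both genotypes share. Of 207850 unchanged probe sets, 2 were called without the block and 53 with it. The simulated spread was likely too wide, as described under Other observations, so these recovery rates may be too low for the real arrays. Camera was run on 20 simulated data sets of 14662 genes for the same comparison. It found the list of 55 auxin genes, shifted by 0.5 log2 units, in 20, and called 0 of 540 unshifted lists. The noise was drawn independently for each gene, so calls due to correlated genes were not tested. Smaller lists, smaller shifts, camera with an estimated correlation and fry were not simulated.

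The themes of 33 gene lists, the tests, the alternatives and the rule for named genes were set before the data were examined. The lists had been written as patterns in gene descriptions, which the tables used here lack, so their members were matched again by symbol and synonym, after the value table had been opened but before any gene's values were looked at. Of the 33 lists, 29 had at least 5 measured genes. The others, with 0 to 4 measured genes, covered circadian clock, disease resistance, receptor kinase and transposon genes and were not tested. The rule for named genes took the 12 largest changes in each direction among genes past the threshold, or, with fewer than 10 such genes, the 10 with the smallest p in each direction. For each list described it took up to 4 members past the threshold, or, where none passed, up to 2 with the smallest p. SPL14 and LAX1, further members without overlap between the genotypes, were added after their values were seen.

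Whether replicate numbers pair the arrays was decided before the fits were compared. The series text states 2 repetitions of the experiment and both genotypes have replicates 1 and 2, although the labels do not say outright that a number marks a repetition. Deviations of same-numbered arrays from their genotype's mean correlated across probe sets, with Pearson's r = 0.595 and Spearman's rho = 0.425. The alternatives were quantile normalization, median centring, filters at the 25th percentile and at the median of the probe set means, an intensity trend with a robust prior, the repetition as a block, leaving out each array, a minimum log2 difference of 1 and the mean of a gene's probe sets. Alternatives added after seeing the data were leaving out probe sets that name several genes, each repetition's pair alone, the block with an estimated correlation and leaving out RBBI3.3. The gap of at least 2-fold between genotypes the comparison of the repetitions and its named genes, and groups of genes sharing a symbol stem were also added after seeing the data. Figures were drawn with matplotlib 3.10.9.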

Results

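Gene expression was measured in the stem base of young rice plants, the part of the shoot from which tillers and crown roots emerge. The plants belonged to 2 genotypes of the indica group, called G95 and G160, and were 22 days old at harvest. Each RNA extract pooled 5 stem bases and was hybridised to 1 Affymetrix array, with 2 extracts per genotype and 4 arrays in all. The series describes 2 independent repetitions of the experiment, and replicate numbers 1 and 2 are taken here as repetition 1 and repetition 2 in both genotypes. The value table holds 41770 probe sets, of which 15299 name 1 gene, 436 name several and 26035 have no gene in the annotation used. After keeping the brightest probe set of each gene, 14662 genes were compared. The 4 arrays had nearly equal medians, from 3.77 to 3.80 log2 units, and their small number limits the precision of every comparison.

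The comparison asks which genes differ in stem base expression between G160 and G95. The gene pinA was far apart, at 9.21 ± 0.10 log2 units in G160 and 3.08 ± 0.58 in G95 (SD, n = 2 each). RBBI3.3, a Bowman-Birk type trypsin inhibitor gene, was at 9.19 ± 0.35 in G160 and 6.58 ± 0.45 in G95 (SD, n = 2 each). In the other direction, TPP7, a trehalose-6-phosphate phosphatase gene, was at 4.28 ± 0.34 in G160 and 7.25 ± 0.52 in G95. RYMV1, which encodes an isoform of the translation initiation factor eIF4G, was at 4.85 ± 0.07 in G160 and 7.10 ± 0.49 in G95. None of these genes passed the limma test after Benjamini-Hochberg adjustment, with adjusted p = 0.198 for pinA and adjusted p = 1 for RBBI3.3.

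At the level of probe sets, limma called 0 of 41770 at an adjusted p under 0.05, the smallest adjusted p being 0.0501. That smallest value belonged to probe set 16514879, which has no gene in the annotation used, with a mean of 8.00 in G160 and 2.20 in G95. At an unadjusted p under 0.05 there were 1351 probe sets, 731 higher and 620 lower in G160, where 2088.5 would be expected by chance. In this fit the difference between repetitions counts as spread within a genotype, which can lower the count. With the repetition as a block, limma again called 0 probe sets, and 3061 had an unadjusted p under 0.05, above the same 2088.5. Among the 14662 genes, 0 passed in either fit. At an unadjusted p under 0.05 there were 343 genes without the block and 1119 with it, where 733.1 would be expected by chance. The smallest adjusted p among genes was 0.198 without the block and 0.0867 with it. An intensity trend with a robust prior called 1 probe set, the same one.

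The 10 genes with the smallest p in each direction were named by a rule set before the data were examined, and none of the 20 passed. Higher in G160 besides pinA and RBBI3.3 were LOC4336164, by 4.67 ± 0.29 log2 units (SE), and LOC4333636, by 3.71 ± 0.20. LOC4328990 differed by 2.97 ± 0.19, LOC4347027 by 2.60 ± 0.16, LOC4350344 by 2.34 ± 0.21 and LOC4337001 by 2.33 ± 0.17. LOC9267194 and LOC4338062 differed by 1.94 ± 0.23 and 1.86 ± 0.20. Of the lower genes, LOC4345410 had the widest difference, -5.58 ± 0.31, from 9.99 in G95 to 4.41 in G160. LOC4325989 differed by -3.27 ± 0.26, LOC4345381 by -3.04 ± 0.16, TPP7 by -2.97 ± 0.35 and LOC4350705 by -2.62 ± 0.26. LOC4332974 differed by -2.40 ± 0.25, RYMV1 by -2.26 ± 0.29 and LOC4336558 by -2.01 ± 0.21. LOC4342223 and LOC4326704 differed by -1.77 ± 0.22 and -1.68 ± 0.21. For 12 of the 20 genes, pinA, LOC4336164 and LOC4333636 among them, the dimmer genotype's mean lay below the median of all probe sets, 3.79. Without detection calls such a level is not separated from background, and where it is background the difference is a lower bound. Within the repetitions, pinA differed by 6.47 in repetition 1 and 5.79 in repetition 2, and LOC4345410 by -5.04 and -6.12. With the repetition as a block, limma gave an adjusted p of 0.0867 for pinA and LOC4333636 and 0.0950 for RBBI3.3, LOC4336164, LOC4345381, LOC4345410, LOC4347027 and LOC4349058. The last of these lay outside the rule and was picked after its values were seen.

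**Figure D1:**
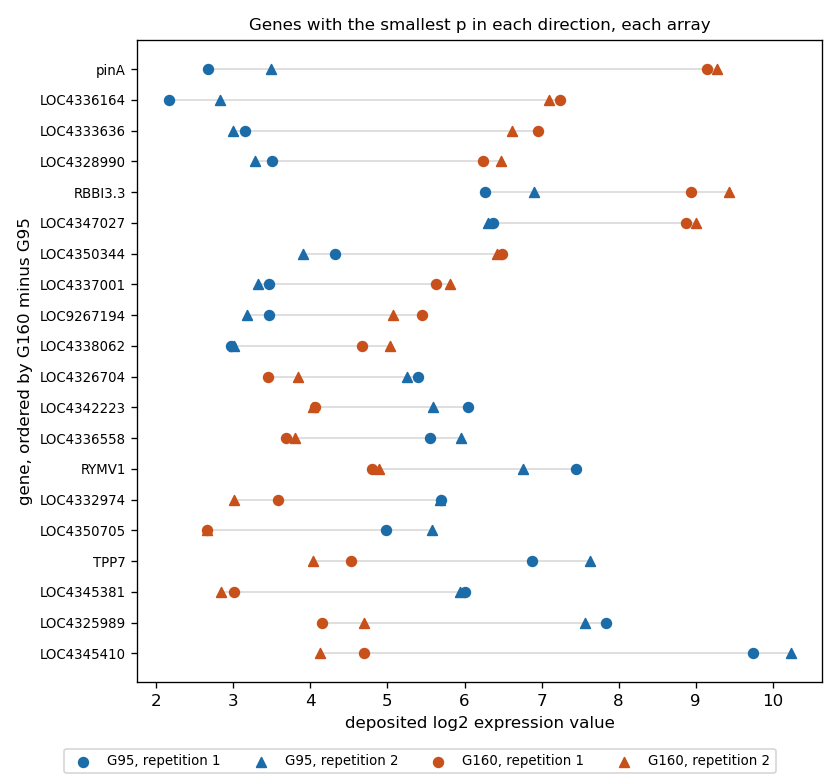
Deposited log2 value (horizontal axis) of the 20 genes with the smallest p in each direction (vertical axis), with 1 point per array, coloured by genotype and shaped by repetition. For pinA the G160 arrays lie at 9.14 and 9.28 and the G95 arrays at 2.67 and 3.49, and for every gene shown the 2 genotypes do not overlap.

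A gap of at least 2-fold between the closest values of the 2 genotypes, a criterion chosen after seeing the data, was met by 149 probe sets, 78 higher and 71 lower in G160. It was met by 58 genes, 30 higher and 28 lower in G160, and 16 of these had a gap of at least 4-fold. The dimmer genotype's mean lay below the median of all probe sets for 27 of the 58 genes and for 9 of the 16. Of the 58 genes, 10 have a name other than a locus number. These include Lsi2, a silicon efflux transporter gene, at 6.03 ± 0.03 in G160 and 7.27 ± 0.16 in G95, and PLP2, at 6.23 ± 0.20 and 4.88 ± 0.18 (SD, n = 2 each). Agglutinin was at 4.37 ± 0.15 in G160 and 7.15 ± 1.86 in G95, so its difference of -2.79 ± 0.94 rests on widely spread G95 values. Lsi2, PLP2 and Agglutinin were picked after their values were seen. The arrays can also be paired in 2 other ways: by repetition, 424 genes showed such a gap, and in the crossed pairing 1 gene did. Without any gap, the genotypes did not overlap for 3744 genes, or 25.5%, where 33.3% is the share that chance gives for 2 against 2 exchangeable arrays. With the repetitions apart, the arrays are not exchangeable: the share was 53.4% by repetition and 20.8% in the crossed pairing.

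Of the gene lists chosen before the data were examined, 1 of the 29 with at least 5 measured genes passed camera at the preset correlation. It was the list of pathogenesis-related and antimicrobial proteins, which was higher in G160 (median 0.29 log2 units over 19 genes, camera adjusted p = 0.00665). The call was lost at an adjusted p = 0.996 in camera with an estimated correlation, and fry gave an adjusted p of 0.999. With 2 residual degrees of freedom, camera with an estimated correlation had little power, and all 29 lists shared that adjusted p. The call thus rests on the preset correlation, and its loss says little about the list. Of its 19 genes, 13 were higher and 6 lower in G160, 7 without overlap above and 2 below. The count past 0.05 was 0 over all genes and 1 adjusted over the list alone, which was RBBI3.3. GER1, a germin-like protein gene, was at 8.36 ± 0.29 in G160 and 7.63 ± 0.07 in G95 (SD, n = 2 each). Without RBBI3.3, a test added after seeing the data, the median was 0.28 and the camera adjusted p = 0.0880. The list's median was 0.07 in repetition 1 and 0.54 in repetition 2, and without the second G160 array, which also unbalances the repetitions, the list did not pass (median 0.02, camera adjusted p = 0.355).

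Genes tied to tillering and root initiation, the organs that the stem base forms, gave no call as lists. For the 10 strigolactone and tillering regulators the median difference was 0.20 (camera adjusted p = 0.495), and within repetitions 1 and 2 the medians were 0.04 and -0.02. D14, the strigolactone receptor gene, was at 7.37 ± 0.19 in G160 and 6.66 ± 0.08 in G95 (SD, n = 2 each), and CCD8A, also named D10L, at 5.03 ± 0.21 and 4.37 ± 0.21. LAX1, which acts in axillary meristem formation, was at 4.52 ± 0.19 in G160 and 5.01 ± 0.15 in G95, and SPL14 at 3.90 ± 0.06 and 4.12 ± 0.16. The count past 0.05 was 0 over all genes and 0 adjusted over the list alone, or 2 adjusted over the list alone with the repetition as a block. For the 12 root initiation regulators the median was -0.15 (camera adjusted p = 0.736). WOX11, an activator of crown root growth, was at 7.01 ± 0.22 in G160 and 6.68 ± 0.20 in G95, and WOX5 at 3.34 ± 0.14 and 3.54 ± 0.04. The 55 auxin genes had a median of -0.03 and the 31 cytokinin genes one of -0.02, both with a camera adjusted p of 0.994. LOGL1, a cytokinin activating enzyme gene, was 0.60 ± 0.16 (SE) log2 units higher in G160.

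Most cell cycle and ribosomal protein genes were lower in G160, without a call in the fit of genotype alone. The 60 cell cycle and DNA replication genes had a median of -0.23, with 51 lower and 9 higher in G160 (camera adjusted p = 0.231), and the 16 ribosomal protein genes a median of -0.20, with 15 lower (camera adjusted p = 0.495). With the repetition as a block both lists passed camera, at adjusted p = 8.98e-05 for cell cycle and 0.0233 for ribosomal proteins, and both were lost at an adjusted p = 0.970 with an estimated correlation. The pathogenesis-related list had a camera adjusted p of 0.00286 with the block and 0.970 with an estimated correlation in that fit. With the block, camera with an estimated correlation rests on 1 residual degree of freedom and could hardly call any list. The 3 calls with the block thus hold at the preset correlation only. For cell cycle genes the G160 minus G95 median was -0.31 in repetition 1 and -0.07 in repetition 2. Leaving out 1 array unbalances the repetitions, so that part of the difference between them enters the genotype comparison. Without the first G95 array the cell cycle median was then 0.24 (camera adjusted p = 0.00876), and without the second it was -0.70 (camera adjusted p = 5.4e-11). The kinesin gene KIN14B differed by -1.42 ± 0.71 and the cyclin gene CYCD5-1 by 0.31 ± 0.16 (SE). The 7 histone genes had a median of -0.19, and the 15 shoot meristem and leaf primordium regulators one of -0.12 (camera adjusted p = 0.848 and 0.638). Among the meristem list, GRF1, a growth-regulating factor gene, was at 4.80 ± 0.09 in G160 and 5.54 ± 0.16 in G95, and HOS66 at 6.68 ± 0.12 and 6.26 ± 0.13 (SD, n = 2 each).

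The other hormone, defence and nutrient lists gave no call. The 24 jasmonate genes had a median of 0.21, with 19 higher in G160 (camera adjusted p = 0.318). JAZ1, a repressor of jasmonate responses, was at 8.56 ± 0.02 in G160 and 7.84 ± 0.01 in G95, and NINJA1 at 5.98 ± 0.52 and 6.90 ± 0.02 (SD, n = 2 each). The 10 gibberellin genes had a median of -0.02, the 8 ethylene genes 0.08, the 26 dehydrin and abscisic acid genes 0.01 and the 9 diterpenoid phytoalexin genes 0.05. ACO1, of ethylene synthesis, differed by -0.64 ± 0.19 (SE). The 29 iron genes had a median of 0.02, and YSL15, an iron-phytosiderophore transporter gene, differed by 0.94 ± 0.32. The 21 phosphate genes had a median of -0.03 and a mean of -0.15, the 14 nitrogen genes a median of 0.09 and the 17 aquaporins one of -0.09. The aquaporin gene TIP4-1 was 0.47 ± 0.15 higher in G160. With the repetition as a block, 1 aquaporin passed adjusted over the list alone. It was not TIP4-1, whose unadjusted limma p in that fit was 0.0307.

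Carbohydrate, wall and tissue marker lists gave no call. The 39 starch, sucrose and sugar transport genes had a median of 0.01. Of them, AGPS2, a small subunit of ADP-glucose pyrophosphorylase, was at 5.10 ± 0.17 in G160 and 6.16 ± 0.0038 in G95, and SS1, a starch synthase gene, at 3.51 ± 0.09 and 4.31 ± 0.05 (SD, n = 2 each). The 40 expansin and xyloglucan enzyme genes had a median of 0.01, the 26 cellulose synthase and COBRA genes -0.02, the 24 lignin genes 0.00, the 5 peroxidases -0.17 and the 6 glutathione transferases -0.01. The 31 flowering and MADS-box genes had a median of 0.00, with MADS16 at 5.10 ± 0.10 in G160 and 4.11 ± 0.08 in G95 and MADS56 at 8.01 ± 0.17 and 6.99 ± 0.59. The 37 heat shock genes had a median of 0.03. Green tissue was represented by 10 photosynthesis genes, with a median of -0.12 and CAB2R at -0.54 ± 0.17 (SE). For other tissues, the 20 endodermis and root genes had a median of -0.01 and the 6 seed storage genes one of -0.05. The mean was above 0 and the median below it for the endodermis and root list (0.0032 and -0.0093), the glutathione transferases (0.07 and -0.01) and the flowering list (0.01 and -0.0016). Over the 28 lists that did not pass, camera's adjusted p ran from 0.231 to 0.994.

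Summed over probe sets, the repetitions differed more than the genotypes did. A gap of at least 4-fold was met by 33 probe sets and 22 genes between repetitions, against 37 and 16 between genotypes. Of the sum of squares between arrays, 57.6% lay between repetitions, 27.4% between genotypes and 14.9% in their interaction, and the first principal component (61.8%) separated the repetitions. Across probe sets, which are not independent replicates, repetition 1 of G95 correlated more closely with repetition 1 of G160 (0.982) than with repetition 2 of G95 (0.966). Comparing repetition 2 with repetition 1 and ignoring genotype, limma called 166 of the 14662 genes, 59 higher and 107 lower in repetition 2, but 0 of the 41770 probe sets, the smallest adjusted p being 0.0681 with 6702 at an unadjusted p under 0.05. With genotype in the fit of genes it called 0, the smallest adjusted p being 0.0522, with 3648 genes at an unadjusted p under 0.05. The 60 cell cycle genes were lower in repetition 2, with a median of -0.85 (camera adjusted p = 6.14e-14) and 50 lower in both genotypes. The 16 ribosomal protein genes had a median of -0.89 (camera adjusted p = 7.85e-08) and the 7 histone genes -0.66 (camera adjusted p = 0.00505). Higher in repetition 2 were the jasmonate list, with a median of 0.44, the phosphate list, 0.30, and the heat shock list, 0.14 (camera adjusted p = 0.00587, 0.00479 and 0.0403). None of the 6 lists passed camera with an estimated correlation (adjusted p = 0.732). That test rests on 1 residual degree of freedom here and could hardly call any list. The 6 calls thus hold at the preset correlation only, and their loss says little about these lists. Within G95 the cell cycle median was -0.80 and within G160 it was -0.81.

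**Figure D2:**
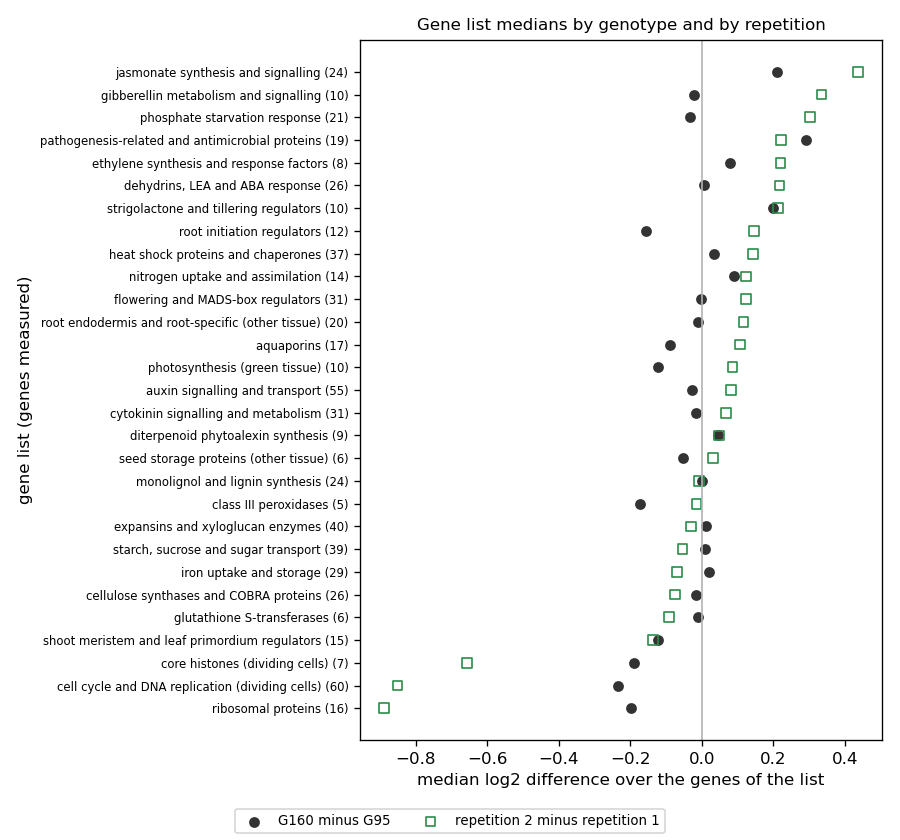
Median log2 difference (horizontal axis) over the genes of each of the 29 gene lists (vertical axis, with the number of genes measured), for G160 minus G95 (filled circles) and repetition 2 minus repetition 1 (open squares). The genotype medians run from -0.23 to 0.29, while the repetition medians of the ribosomal protein and cell cycle lists lie at -0.89 and -0.85.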

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

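The gap counts, the comparison of repetitions and the settings named as added below were chosen after seeing the data. The 48 named genes gave 526 values under the alternatives, all with the sign of the reported value and none past an adjusted p of 0.05. The sign is fixed by construction where an array is left out, since the genotypes do not overlap for these genes. It is also fixed under the filters, the intensity trend and the block, which leave a gene's log2 difference unchanged. Only quantile normalization, median centring and the mean of a gene's probe sets could change a sign. The count of differing probe sets, 0, became 1, higher in G160, under quantile normalization, under the intensity trend with a robust prior and, as an added setting, without probe sets naming several genes. It was probe set 16514879 each time, with limma adjusted p = 0.0428, 0.0490 and 0.0483 against 0.0501. The replicate block left the counts of probe sets and genes at 0. The list count, 1, became 3 with the replicate block, 0 with an estimated correlation, 0 under fry, 0 with both the block and an estimated correlation, and 0 to 4 with 1 array left out. The pathogenesis-related median, 0.29, stayed at 0.29 under these list tests by construction, with adjusted p = 0.996 with an estimated correlation, 0.999 under fry and 0.970 with the block and an estimated correlation. Camera with an estimated correlation rests on 2 residual degrees of freedom, or 1 with the block, and has little power. For the pathogenesis-related list, the left-out arrays gave a further view of the median. With 1 array left out it ran from 0.020 (without the second G160 array, adjusted p = 0.355) to 0.50, and without RBBI3.3 it was 0.28 at adjusted p = 0.0880. Probe sets with a 2-fold gap, 149, numbered 278 to 714 and genes, 58, numbered 121 to 395 with 1 array left out, where fewer arrays must differ. In repetition 1 alone they numbered 508 and 219, in repetition 2 alone 1089 and 598. With 1 array left out, the cell cycle median ran from -0.70 to 0.24, the ribosomal median from -0.70 to 0.32 and the jasmonate median from -0.13 to 0.54, where the unbalanced repetitions enter the genotype difference. Within repetitions 1 and 2 the medians were -0.31 and -0.07 for cell cycle, -0.13 and -0.32 for ribosomal proteins and 0.01 and 0.42 for jasmonate. A lone array was assumed to vary like the other pair. The 166 genes differing between repetitions became 296 and 428 with the filters, which test fewer genes. Apart from the filters and the left-out arrays, the cause was not tested. The alternatives based on name endings of probe sets and on linear values were not run, since the probe sets are numbered and the values are log2.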

Other observations

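The tests of neighbouring genes and of further probe sets were set before their results were seen, and all other tests and comparisons here were chosen after. Among single genes that differed between the repetitions, CCA1, a morning gene of the circadian clock, was 3.83 ± 0.26 log2 units (SE) higher in repetition 2 (limma adjusted p = 0.0425, genotype ignored, and 0.0522 with genotype in the fit). It was at 6.51 and 10.25 in G95 and at 5.95 and 9.87 in G160. Selected genes of the cell cycle list were lower, with PCNA, the replication clamp, at -2.61 ± 0.25 and the helicase gene MCM7 at -1.64 ± 0.17. The kinesin gene KIN12F was at -2.07 ± 0.20 and the kinase gene CDKB1-1 at -1.35 ± 0.17. The list's own call between repetitions was lost with an estimated correlation (camera adjusted p = 0.732), a test with little power at 1 residual degree of freedom. The aquaporin genes PIP2-2 and PIP1-2 were 1.77 ± 0.14 and 1.42 ± 0.16 higher, while the list of 17 aquaporins that holds both had a median of 0.11 and did not pass between repetitions (camera adjusted p = 0.0642). The limma adjusted p of these single genes without genotype were 0.0425 for PCNA, MCM7, KIN12F and PIP2-2, 0.0497 for CDKB1-1 and 0.0488 for PIP1-2, and none passed with genotype in the fit. SUS1, a sucrose synthase gene, was at -1.67 ± 0.14.

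Of 44 groups of genes sharing a symbol stem, with at least 8 members each, 9 passed between repetitions and 5 are given here. In camera at the preset correlation, 18 genes named KIN, kinesins for the most part, had a median of -0.98 (adjusted p = 1.37e-06), 9 protein disulfide isomerase genes (PDIL) -0.71 (adjusted p = 0.000607), 23 calmodulin-like genes (CML) 0.34 (adjusted p = 0.000328), 10 JAZ genes 1.08 (adjusted p = 0.00291) and 9 genes named PIP, aquaporins except for PIP5K, 0.49 (adjusted p = 0.00291). Between genotypes the same groups had medians of -0.31, -0.03, 0.13, 0.45 and 0.04, with adjusted p = 0.222, 0.941, 0.498, 0.199 and 0.970. Most or all genes of the KIN, JAZ and PIP groups also belong to the cell cycle, jasmonate and aquaporin lists. These groups are thus no observations apart from those lists. An estimated correlation was not run for the 5 groups.

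For 58 genes the genotypes lay at least 2-fold apart, and 3 explanations were tested. Chance separation stays open, since 3 pairings are too few for a share under 0.05. The crossed pairing of the arrays gave 1 such gene and the pairing by repetition 424. Simulated arrays held on average 41.8 unchanged probe sets with such a gap against 149 observed, but that average is no estimate of the chance share. Unchanged simulated probe sets would separate about as often in the crossed pairing. There the real arrays gave 4 probe sets, so the simulated spread was likely too wide. Of the 58, 5 had another such gene within 3 measured genes (1.32 expected, one-sided permutation p = 0.0303), and LOC4326000, pinA and RBBI3.3 are 3 of them, all higher in G160, while LOC4345832 and PLP2 are the others. That is consistent with linked blocks or structural variants for those 5 genes, but adjacent copies of 1 family sharing probe signal would look alike, and the other genes had no such neighbour. Probe mismatch cannot be told apart from a change in transcript level, since only 4 further probe sets exist and their median ratio to the first was 0.498 (LOC4327842 2.19 against 2.87, LOC4350705 -0.81 against -2.62), so a difference between the genotypes stays open as well.

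The lower cell cycle and ribosomal protein values in repetition 2 were weighed against 3 explanations. An aberrant array in 1 genotype alone is argued against by the smallest drop of the 2 lists in either genotype, -0.77. A normalization shift common to all genes of an array would leave the gap to the other genes at 0. The gap was -0.85 for cell cycle (95% bootstrap interval -1.11 to -0.62) and -0.89 for ribosomal proteins (-0.99 to -0.83). These intervals resample genes, not arrays, and do not measure the spread between repetitions. Such a shift cannot make this pattern, but the lists were picked for lying below the other genes, so the gap is no separate test. A shift that differs between genes was not tested. Less dividing and young tissue in repetition 2 may account for it, but stays undecided. The 15 shoot meristem regulators had a median of -0.14 (95% bootstrap interval over genes -0.27 to 0.03), with members going both ways. That interval lies above the cell cycle, ribosomal protein and histone medians, -0.85, -0.89 and -0.66, so these regulators did not fall alike. The endodermis and root list had a median of 0.12 (0.01 to 0.27) and the photosynthesis list 0.09 (-0.09 to 0.38). The rule for this test was made stricter after its first result was seen. The added condition, that the meristem interval also lies below 0, was not met, and it alone leaves the test undecided. An interval that reaches 0 does not speak for the explanation. The other conditions were met, so the values argue against a fall that these 15 regulators share with the cell cycle genes. Whether dividing cells were fewer without such a shared fall was not tested. No biological explanation of a difference between repetitions is named by the design.

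CCA1 was higher in repetition 2 in both genotypes, the smaller difference being 3.75, so its difference does not rest on 1 array. That is no separate test, since CCA1 was picked from a fit that favours genes alike in both genotypes. Another time of day at harvest is a candidate explanation. GI, an evening clock gene, differed by -1.09 in each genotype (-1.09 ± 0.16, limma adjusted p = 0.0544, and 0.0473 among probe sets at or above the median level), but PCL1, also an evening gene and added to the test after its values were seen, went both ways, at 0.77 in G95 and -0.43 in G160, and PRR37 was at -0.04 and -0.23. The clock list was chosen before the data were examined and had too few measured genes to test, and the hour of harvest is not given in the sources used here.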
